A study of Mus musculus with 17 samples.

How the data were processed

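H3K27ac was profiled in mouse hypothalamus, per the labels, in 3 bulk CUT&Tag samples titled as biological replicates and in 7 pairs of Paired-Tag DNA and RNA sub-libraries, whose antibodies were against H3K27ac and H3K27me3. Samples were grouped by their titles. Only the peak list of the bulk samples was analysed, and the Paired-Tag matrices were not analysed here. Per the labels' protocols, nuclei of dissected tissue were incubated with the antibody and Tn5 fused to protein A, and libraries were sequenced as paired ends on an Illumina instrument. The submitters' processing notes name MACS2 without a version, BWA 0.7.17, cutadapt 4.5, STAR 2.7.10a, UMI-tools 1.1.4 and the genome build mm10, with no role or order. The caller's settings, its background and any filter of repeats or blacklisted regions are not given in the sources used here. The deposited list is named an optimal overlap set of peaks, but the rule that combined the replicates is not spelled out.

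The deposited list gives a position, a score, a fold enrichment (a linear ratio), a −log10 p, a −log10 q and a summit offset per peak, in columns without header, read by their order in the narrowPeak format. The score deposited by the authors equalled 10 times the −log10 p, truncated to a whole number and held at 1000, in 99.9946% of lines. The fold ratio deposited by the authors is a value of each peak and was used only to rank or describe peaks within this list. The −log10 p and −log10 q values deposited by the authors served to rank peaks and to define a stricter set. Peaks were given for the 3 samples together, so replicates could not be compared, nothing could be left out in turn, and no spread between animals exists. The unit of each test was a gene, a peak or a chromosome. The p-values therefore do not measure the spread between animals, neighbouring genes are not independent replicates, and Wilson intervals cover counting error only. Depth is unknown, and a gene without a peak had none in the deposited list. Numbers missing from the peak names leave open that some called peaks were left out of it.

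Genes came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 denotes, with 49943 genes on the chromosomes of the list, of which 21887 were protein-coding. The table gives the span of each gene but no strand, transcripts or exons. The design fixed before the data were examined called for transcript starts. A gene was instead called marked when any peak overlapped 1 kb either side of an end of its span. This includes 3' ends and promoters of adjacent genes and misses promoters inside a gene. Classes of exon and intron, 27 sequence motifs and CpG content need sequence or transcripts and were not run. Coordinates are 1-based in mm10.

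The 22 gene lists, with 10 to 39 genes each, were fixed at the same time as the tests: hypothalamic neuropeptides, 4 sets of regional transcription factors (hypothalamic, cortical, hindbrain and midbrain, Hox), pan-neuronal genes, neurotransmitter identity, hormone and peptide receptors, circadian clock, immediate early genes, astrocyte, tanycyte and ependymal, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural and fibroblast, pituitary, choroid plexus, blood and lymphocyte, other organs and housekeeping. All 479 distinct genes were matched by symbol, and 1 gene, Rax, is in 2 lists. Several lists hold genes that other cell types also express. Near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt) are uncertain, since reads may be shared between them.

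Marked shares were compared with all other protein-coding genes by Fisher's exact test, two-sided. The median of the highest fold at the ends of marked genes was compared with 10000 random lists of marked genes by a two-sided permutation test. Distal peaks, with a summit more than 2500 bp from every gene end, went to the nearest end within 100 kb, and their mean per gene was compared with 10000 random lists matched on the decile of the territory's length. The median percent of the gene span and 10 kb flanks covered by peaks was compared with random lists matched on the decile of gene length. Distal peaks closer than 12.5 kb were joined, ranked by covered bp, and the genes nearest to the top 500 domains were counted by list with Fisher's exact test. The X chromosome was compared with the 19 autosomes by an exact permutation over chromosomes. Intervals and the gaps between them were permuted within each chromosome 100 times. P-values were adjusted by the Benjamini-Hochberg method over the 22 lists within each of 5 measures, so the adjustment does not cover the 110 tests together. With 24 alternatives, 638 list tests were run in all. Calls used an adjusted p under 0.05. The 21 pairs of lists and the 20 gene families were chosen after the shares were seen, each with its own adjustment.

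Genes named in the text followed a fixed rule, and not every gene under it is named: in each list the 3 marked members of highest fold and up to 3 members without a peak at an end in alphabetical order, 22 genes of hypothalamic interest, the gene nearest to each of the 20 domains with the most covered bp, and the gene nearest to each of the 10 peaks of highest fold. Genes of X and Y, and genes sharing a peak with a listed gene, were named after their values were seen. Sharing was checked only for the highest peak at an end, so a peak inside a gene may lie at an end of another gene.

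The 5 list measures were tested on simulated data, shuffled peaks with peaks planted at the genes of 5 lists of 20. A sparse planting, of 1 peak at an end and 10 upstream, was called in 5 of 5 lists by share and 5 of 5 by fold, but in 1 of 5 by distal peaks, 1 of 5 by coverage and 0 of 5 by domains (5, 5, 0, 0 and 0 of 5 with 10 of 20 genes planted). A dense planting, with a peak every 2500 bp over the gene and its flanks, was tried after that result, and was called in 5 of 5 lists by every measure. With 10 of 20 genes planted densely, 5, 5, 3, 5 and 3 of 5 lists were called in the same order of measures. None of the 12 unplanted lists was called by any measure. Planted folds lay above the median of really marked genes, 8.60, and shuffled peaks had 3.16% of summits at gene ends against 9.13% in the list. Recovery by share and fold was therefore easier here than in the real list. Results of any of the 5 measures that did not pass leave room for moderate differences.

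Alternatives covered other windows, stricter peak sets, peak width or −log10 q in place of fold, other reaches and flanks, other domain rules, the interval midpoint in place of the summit, and chromosome X left out. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.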

Results

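The data described here are H3K27ac profiles of mouse hypothalamus, the ventral forebrain region that controls feeding, fluid balance, reproduction and the endocrine axis. H3K27ac is acetylation of lysine 27 on histone H3, a mark of active promoters and enhancers, and it was mapped by CUT&Tag, in which an antibody tethers the Tn5 transposase to marked chromatin. The 17 samples fell into 3 groups: 7 DNA sub-libraries and 7 RNA sub-libraries of Paired-Tag, a single-nucleus assay that reads a histone mark and RNA from the same nucleus, and 3 bulk CUT&Tag samples described as biological replicates. A single peak list shared by the 3 bulk samples was analysed, and the Paired-Tag matrices were not analysed here. The list carried no value per replicate and no read counts, so the depth behind each peak is unknown and no spread between animals could be given. The question addressed was which genes of the hypothalamus, of its cell types and of other tissues carried the mark.

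The list held 183678 intervals on chromosomes 1 to 19, X and Y, and none overlapped or touched another. Their median width was 557 bp, with a range of 147 to 4216 bp, and together they covered 126.687 Mb, or 4.65% of the annotated span of these chromosomes in build mm10. The fold enrichment given by the authors' peak caller had a median of 3.18 and ran from 1.31 to 27.97. All peaks but 1 had a q of at most 0.05, and that peak had a q of 0.118. The peak names ran up to number 295763, and 62.1% of those numbers were present. The share present fell from 99.9% among the first 20000 numbers to 0.679% among the last, and the median fold of the peaks present fell from 8.42 to 1.88.

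H3K27ac peaks lay in and at the ends of protein-coding genes far more often than shuffled intervals did. Summits within 1 kb of an end of a protein-coding gene made up 9.13% of peaks (16768 of 183678, Wilson 95% interval 8.998 to 9.26), against 3.16% ± 0.0575 (SD, n = 100 shuffles). Summits inside genes but away from the ends made up 62.1% against 39.3% ± 0.297, and intergenic summits 22.03% against 49.3% ± 0.305. Genes of other kinds, such as long noncoding RNAs and pseudogenes, held 6.70% against 8.24% ± 0.144. For each class the observed value lay outside the range of the 100 shuffles, which permuted intervals and the gaps between them within each chromosome and took no account of mappability. Peaks at gene ends were also stronger and wider: their median fold was 6.71 and their median width 1077 bp, against 3.11 and 528 bp for the 157805 peaks more than 2500 bp from every gene end. Among 21887 protein-coding genes, 15147 (69.2%, Wilson 95% interval 68.6 to 69.8) had a peak within 1 kb of an end, 46.1% at 1 end and 23.1% at both. The gene table gave no strand, so an end may be the start or the 3' end of the gene.

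Hindbrain, midbrain and Hox transcription factors were marked less often than hypothalamic factors. Of 36 hypothalamic transcription factor genes, 29 (80.6%, Wilson 95% interval 65.0 to 90.2) had a peak at an end, against 6 of 15 hindbrain and midbrain factors (40.0%, 19.8 to 64.3) and 2 of 39 Hox genes (5.13%, 1.42 to 16.9), which specify hindbrain and spinal cord segments. Rax, needed for the eye field and tanycytes, had a fold of 8.61, and Vax1 had 5.59. Nkx2-1, a determinant of ventral hypothalamus on chromosome 12 (56531935 to 56536908), had a fold of 3.83. Among other factors with hypothalamic roles, Otp had 5.49, Isl1 5.05, Sim1 4.63 and Six3 1.64, while Barhl1, Ebf3, Hmx2 and Nr5a1 had no peak at an end. Ebf3, Hmx2 and Nr5a1 had peaks inside the gene, 9, 1 and 4 of them, with highest folds of 5.27, 5.39 and 3.49. The 7 peaks overlapping the span of Six3 had a highest fold of 3.86.

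Only the lower shares passed the test among these regional lists. Against all other protein-coding genes, of which 69.3% were marked beside the Hox list, the Hox share was lower (Fisher's exact test, two-sided, adjusted p = 8.87e-16), as was that of the hindbrain and midbrain factors (exact adjusted p = 0.0443). The hypothalamic list was not distinguishable from other genes (exact adjusted p = 0.240), nor was the cortical list, with 10 of 15 marked (66.7%, exact adjusted p = 0.823). Tested directly, the hypothalamic share was 40.6 percentage points above the hindbrain and midbrain share (95% interval 11.7 to 62.9, exact adjusted p = 0.0203 over 21 pairs of lists chosen after the shares were seen). It was 75.4 points above the Hox share (55.9 to 85.8, exact adjusted p = 1.17e-10), and 13.9 points from the cortical share, with an interval of -10.0 to 40.7 (exact adjusted p = 0.396). Hoxd1 had a fold of 6.21, while Hoxa10, Hoxa11 and Hoxa13 had no peak at an end. Cortical factors with a peak included Bhlhe22 (fold 7.05), Lhx2 (6.21) and Neurod6 (5.06), and Emx1, Eomes and Fezf2 had none at an end. Emx1 and Fezf2 had 1 and 3 inside the gene, with highest folds of 2.02 and 4.51. In the hindbrain and midbrain list, Ptf1a had 9.10, En2 6.23 and Phox2a 4.39, and Atoh1 and Lbx1 had none. The Phox2a peak also reached an end of Inppl1. The lower share of the hindbrain and midbrain list was lost with windows of 2500 bp (46.7% against 73.6%, exact adjusted p = 0.0576) and in 3 further settings. The hypothalamic list passed as higher with those windows (94.4% against 73.6%, exact adjusted p = 0.00752), but lay below other genes among peaks above the median −log10 q (55.6% against 64.4%, exact adjusted p = 0.384). With only peaks at or above the upper quartile of fold its share lay further below.

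**Figure D1:**
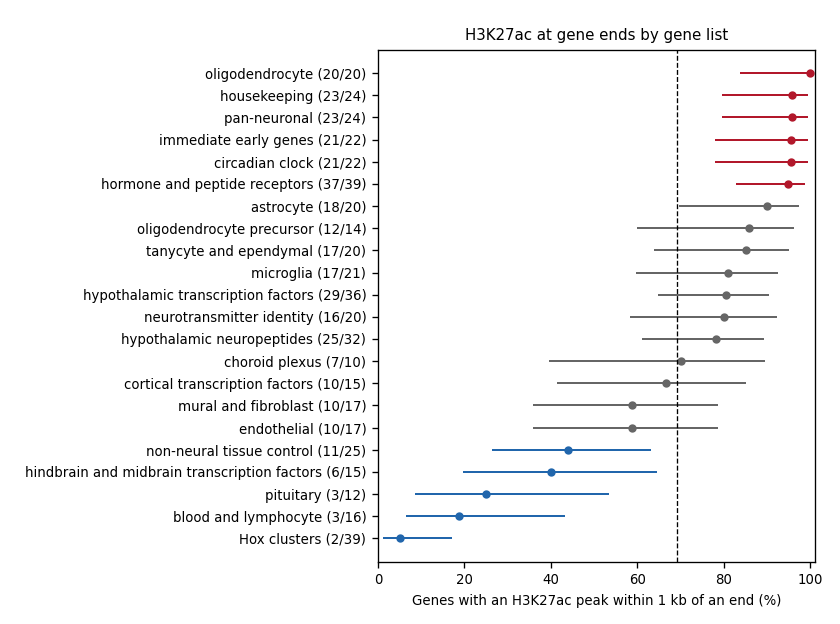
Percent of the genes of each of 22 lists with an H3K27ac peak within 1 kb of an end (points) with Wilson 95% intervals (lines, counting error only). Red lists were higher and blue lists lower than all other protein-coding genes at an adjusted p under 0.05, grey lists did not pass, and the dashed line is the 69.2% of all genes, with Hox clusters lowest at 5.13%.

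Most genes for hypothalamic peptides carried the mark, with wide differences in fold. Of 32 neuropeptide genes, 25 (78.1%, Wilson 95% interval 61.2 to 89.0) had a peak at an end, which was not distinguishable from other genes (exact adjusted p = 0.421). Pomc, the precursor of melanocortins that suppress feeding, had the highest fold of the list, 14.8, at its higher-coordinate end on chromosome 12 (3959621 to 3960882). No other peak lay in its span or at its ends, and the gene table does not tell whether that end is its start or its 3' end. Rln3 followed with 11.2 and Agrp, the feeding-promoting antagonist of melanocortin receptors, with 9.70, but those peaks also lay within 1 kb of an end of Il27ra and Atp6v0d1, so their gene is uncertain. Crh, which drives the stress axis, had 6.36, the orexin gene Hcrt 5.84, Npy 5.27, Kiss1 3.83 at a peak that also reached Golt1a, Trh 3.76 and Sst 3.54. Avp and Oxt, which encode the neurohypophysial hormones and lie side by side on chromosome 2, had 2.67 and 2.56. Gnrh1, Pmch, Adcyap1 and Nms had no peak at an end, and the nearest peak lay 6255 bp from Gnrh1, 54242 bp from Pmch and 22542 bp from Nms. Adcyap1 had 2 peaks inside the gene, with a highest fold of 3.64. Among peaks above the median −log10 q the share of the list lay below that of other genes (62.5% against 64.4%, exact adjusted p = 0.854). With only peaks at or above the upper quartile of fold it lay further below.

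**Figure D2:**
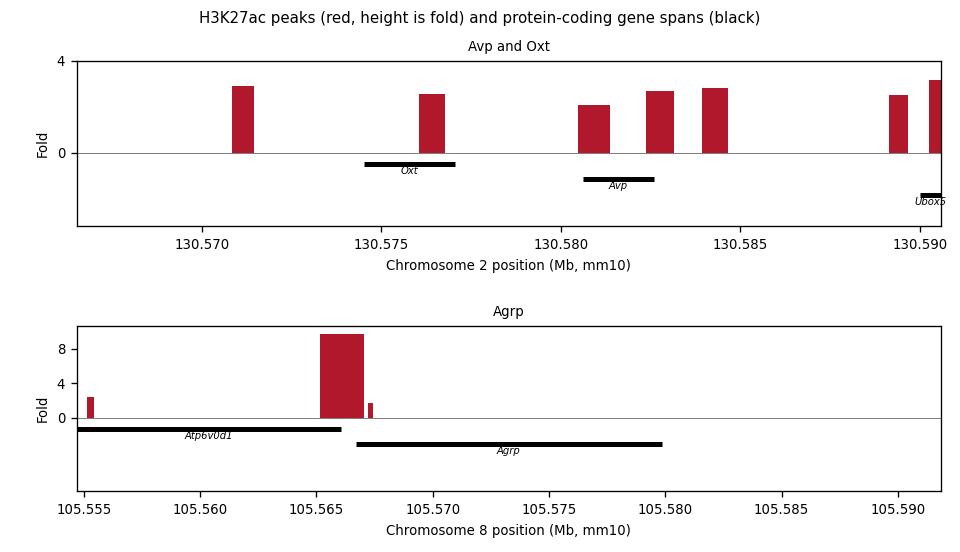
Peaks (red boxes, height is the caller's fold) and protein-coding gene spans (black bars) around Avp and Oxt and around Agrp, by position in Mb of mm10. Folds at the ends of Avp and Oxt were 2.67 and 2.56, and the Agrp peak of 9.70 also reached Atp6v0d1.

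Receptors for hormones and peptides were marked more often than other genes. In that list 37 of 39 genes (94.9%, Wilson 95% interval 83.1 to 98.6) had a peak at an end (exact adjusted p = 0.00122). Adipor1 had a fold of 15.8, the kappa opioid receptor gene Oprk1 11.2 and Npy5r 10.9, and the leptin receptor gene Lepr had 5.06, Mc4r 4.84 and Esr1 2.74. The 10 peaks overlapping the span of Esr1 had a highest fold of 8.66. Oprm1 and Pgr had no peak at an end but 18 and 3 inside the gene. With only peaks at or above the upper quartile of fold, the share was 66.7% against 58.6% and the call was lost (exact adjusted p = 0.407). Genes of neurotransmitter identity were marked in 16 of 20 cases (80.0%, exact adjusted p = 0.421), with Slc6a9 at 7.54, the histamine enzyme gene Hdc at 5.77 and Slc18a2 at 5.48. Chat and Slc18a3, which share the cholinergic locus, and the glycine transporter gene Slc6a5 had none at an end. Chat and Slc6a5 each had 4 inside the gene, with highest folds of 5.34 and 8.26. With windows of 500 bp the share of this list lay below that of other genes (60.0% against 65.9%, exact adjusted p = 0.740).

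Among the cell-type lists, only the pan-neuronal and oligodendrocyte lists passed as higher than other genes, and neither was distinguishable from the astrocyte or microglial list. Pan-neuronal genes were marked in 23 of 24 cases (95.8%, Wilson 95% interval 79.8 to 99.3, exact adjusted p = 0.00947), with Elavl4 at 16.5, Syn1 at 13.3 and Syt1 at 11.2, and only Mapt had no peak at an end. All 20 oligodendrocyte genes were marked (83.9 to 100.0, exact adjusted p = 0.00541), led by Qk at 10.6, a peak shared with Gm46608, the myelin gene Mog at 9.03 and Ugt8a at 8.50. Astrocyte genes were marked in 18 of 20 cases (exact adjusted p = 0.0935), tanycyte and ependymal genes in 17 of 20 (85.0%, 0.240), oligodendrocyte precursor genes in 12 of 14 (85.7%, 0.368) and microglial genes in 17 of 21 (81.0%, 0.421), none of which passed the exact test. Endothelial and mural lists each had 10 of 17 genes marked (58.8%, Wilson 95% interval 36.0 to 78.4, exact adjusted p = 0.473), and choroid plexus 7 of 10 (70.0%, exact adjusted p = 1.0). The oligodendrocyte share was 41.2 percentage points above the endothelial share and, by the same amount, above the mural share (95% interval 15.8 to 64.0, exact adjusted p = 0.00992). The pan-neuronal share was 37.0 points above each (11.7 to 60.1, exact adjusted p = 0.0154). It was 5.83 points from the astrocyte share (-11.8 to 26.2, exact adjusted p = 0.680) and 14.9 from the microglial share (-4.81 to 36.1, exact adjusted p = 0.254). The oligodendrocyte share was 19.05 points from the microglial share (-0.678 to 40.0, exact adjusted p = 0.204), and the astrocyte share minus the oligodendrocyte share was -10.0 points (-30.1 to 7.65, exact adjusted p = 0.602). These pairs were tested only on peaks at gene ends. Over the gene span and 1 kb around it, the endothelial share rose above that of other genes, so the gaps to endothelial genes apply to gene ends. The oligodendrocyte share lay below that of other genes with only peaks at or above the upper quartile of fold, 55.0% against 58.6% (exact adjusted p = 0.904). The microglial share lay below that of other genes among peaks above the median −log10 q (47.6% against 64.4%, exact adjusted p = 0.195), where the astrocyte list passed as higher (exact adjusted p = 0.0385).

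Within these lists the strongest astrocyte peaks were at Ntsr2 (8.67), Mlc1 (8.52) and the glutamine synthetase gene Glul (8.38), the first pair at peaks that also reached Lpin1 and Ttll8, while Aqp4 and Slc4a4 had peaks only away from their ends, with highest folds of 9.19 and 11.4 inside the gene. Tanycyte genes included the thyroid hormone deiodinase gene Dio2 at 10.1, and Mia had 10.4 and Col23a1 8.90 at peaks shared with Rab4b and Phykpl. Fndc3c1, Tm4sf1 and Tmem212 had none at an end. Tm4sf1 and Tmem212 each had 7 inside the gene, with highest folds of 4.33 and 3.97. Ptprz1 (9.63), Lhfpl3 (9.47) and Matn4 (8.10) led the oligodendrocyte precursor list, in which Enpp6 and Pdgfra had no end peak but 22 and 3 inside the gene, with highest folds of 10.1 and 7.62. Selplg (8.15) and Sall1 (7.90) were among the microglial genes with a peak, and Ctss, Gpr34 and Itgam had none at an end. Itm2a (9.10), Kdr (7.54) and the glucose transporter gene Slc2a1 (7.02) led the endothelial list, in which Abcb1a, Emcn and Pecam1 had none at an end but peaks inside the gene with highest folds of 11.1, 6.72 and 7.57. Col1a2 had 7.26 and Slc6a13 5.52 in the mural and fibroblast list, and the Vtn peak of 11.1 was shared with Sarm1. Abcc9, Acta2 and Col3a1 had none at an end. Kl had 7.57, Clic6 5.67 and F5 3.97 in the choroid plexus list, and Kcne2, Kcnj13 and Slc4a5 had none at an end, Slc4a5 having 19 peaks inside the gene with a highest fold of 15.3. Whether the peaks inside these genes lie at an end of another gene was not checked.

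Genes of blood, pituitary and other organs were marked less often. Of 16 blood and lymphocyte genes 3 were marked (18.8%, Wilson 95% interval 6.59 to 43.0, exact adjusted p = 0.0005003), of 12 pituitary genes 3 (25.0%, 8.89 to 53.2, exact adjusted p = 0.00912) and of 25 genes of other organs 11 (44.0%, 26.7 to 62.9, exact adjusted p = 0.0196). The erythroid factor gene Klf1 (9.41) was among the marked blood genes, with Cd79a at 1.95 at a peak shared with Arhgef1, and Cd3d and Cd3e had no peak. Tshb had a fold of 10.4, Tbx19 2.98 and Ghrhr 2.92, and the pituitary hormone genes Gh, Fshb and Cga had none at an end. In the list of other organs Sftpc had 10.6 at a peak that also reached Bmp1, Ckm had 7.80 and Apoa1 7.09, and the liver genes Alb, Ahsg and Cyp2e1 had none. The pituitary and other-organ calls were lost when a summit had to lie nearer to the gene than to any other annotated gene (25.0% against 58.4%, exact adjusted p = 0.111, and 40.0% against 58.4%, 0.152), the second also when a summit had to lie in the window (44.0% against 65.8%, exact adjusted p = 0.0720).

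Clock, immediate early and housekeeping genes were marked in nearly every case. The circadian list had 21 of 22 marked genes (95.5%, exact adjusted p = 0.0116), with Clock at 12.2, Per3 at 12.1, a peak shared with Gm38529, and Cry1 at 9.75. The immediate early list, of genes that respond to neuronal activity, also had 21 of 22 (exact adjusted p = 0.0116), with Homer1 at 10.7, Btg2 at 9.06 and Klf2 at 8.57, and lost its call in 3 settings. In 1 of these, with summits nearer to the gene than to any other, the clock list lost its call too (77.3% against 58.4% for each list, exact adjusted p = 0.155). Housekeeping genes had 23 of 24 (exact adjusted p = 0.00947), with Psmb2 at 18.2, Tfrc at 16.6 and Rpl4 at 20.2, the last at a peak shared with Snapc5. Nfil3, Npas4 and Ywhaz were the members without a peak at an end, but each had 5 inside the gene, with highest folds of 5.44, 7.02 and 6.71.

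Where genes of these lists were marked, their folds tended to be lower than those of marked genes at large, whose median was 8.60 ± 4.28 (SD, n = 15147 genes). In 15 of 22 lists the median fold was lower than in random lists of marked genes at an adjusted p under 0.05, and in none was it higher. The median was 3.97 for 17 microglial genes and 4.32 for 29 hypothalamic factors (two-sided permutation test, adjusted p = 0.00220 for each, from an unadjusted p of 0.0002, the smallest that the permutations can give), 4.31 for 20 oligodendrocyte genes (permutation adjusted p = 0.00293), 4.20 for 16 neurotransmitter genes and 5.06 for 25 neuropeptide genes (permutation adjusted p = 0.00704 for each). The other lower medians were 2.98 for pituitary (permutation adjusted p = 0.0295), 3.53 for choroid plexus (permutation 0.0119), 3.98 for hindbrain and midbrain factors, 4.54 for other organs, 4.71 for cortical factors and 4.83 for mural genes (permutation 0.0295 for each), 4.42 for endothelial genes (permutation 0.0231), 5.2 for astrocyte genes (permutation 0.0249), 5.79 for immediate early genes (permutation 0.0334) and 5.81 for receptors (permutation 0.0103). Housekeeping genes had 10.1 (permutation adjusted p = 0.256), pan-neuronal genes 7.46 (0.376), clock genes 6.80 (0.187), tanycyte genes 6.30 (0.148), oligodendrocyte precursor genes 6.17 (0.164), and the few marked blood and Hox genes 6.57 and 4.55 (permutation 0.553 and 0.164). With peak width in place of fold, 6 lists were lower, and pan-neuronal genes had wider peaks, 1722 bp against 1285 bp (permutation adjusted p = 0.00880). Receptors, immediate early and astrocyte genes then lay above random lists, with 1447, 1393 and 1308 bp (permutation adjusted p = 0.180, 0.489 and 0.851).

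Pan-neuronal and oligodendrocyte genes also had more distal peaks than random lists, those whose summit lay over 2500 bp from every gene end. Pan-neuronal genes had 21.8 ± 21.5 distal peaks within 100 kb (SD, n = 24 genes) against 11.5 in random lists matched on the length of the territory (permutation test, adjusted p = 0.0103), and oligodendrocyte genes had 11.7 ± 11.8 (n = 20) against 5.35 (permutation adjusted p = 0.0121). Hox genes had 0.103 ± 0.502 (n = 39) against 1.13 (permutation adjusted p = 0.00440, from 0.0002, the smallest possible), hindbrain and midbrain factors 1.80 ± 3.00 (n = 15) against 8.67 (permutation 0.0103), blood genes 0.125 ± 0.342 (n = 16) against 1.38 (permutation 0.0220) and neuropeptide genes 2.78 ± 3.97 (n = 32) against 6.12 (permutation 0.0462). Elavl4 had 31 distal peaks, Syt1 33 and Mapt 33, Qk 29 and Ugt8a 28, and Pomc 1, Agrp 0 and Crh 0. The other 16 lists did not pass, with adjusted permutation p from 0.150 to 0.996. The pan-neuronal call was lost within 50 kb (13.04 against 8.58, permutation adjusted p = 0.0713), the oligodendrocyte call within 500 kb (13.1 against 6.20, permutation 0.153) the blood call in 2 settings and the neuropeptide call in 3.

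**Figure D3:**
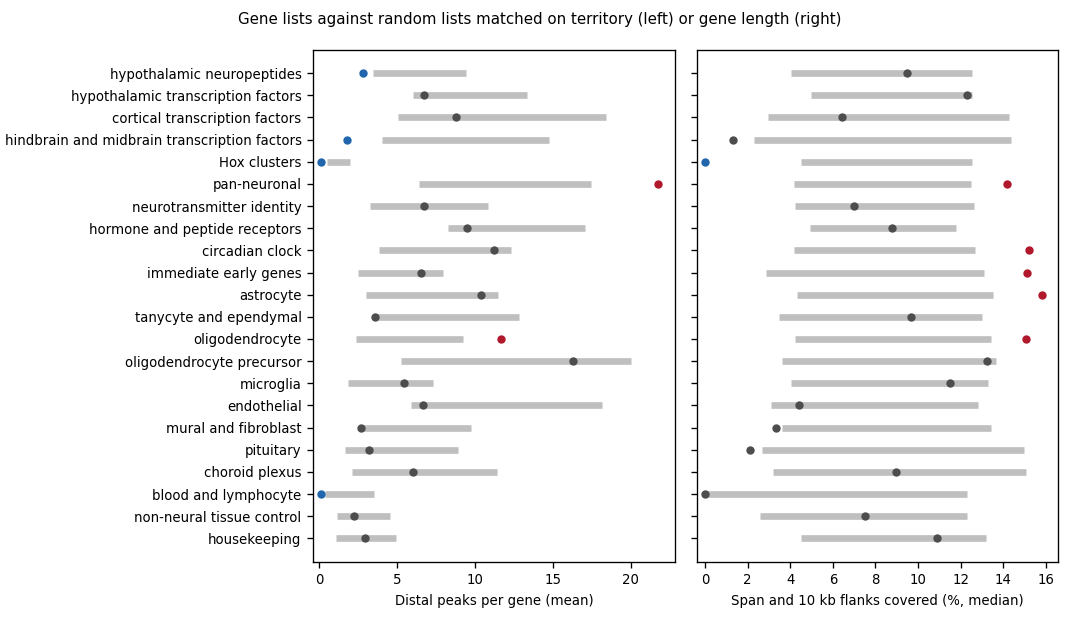
Mean number of distal peaks per gene (left) and median percent of the gene span with 10 kb flanks covered by peaks (right) for 22 gene lists (points), with the central 95% of 10000 random lists (grey bars). Red points were higher and blue points lower at an adjusted p under 0.05, with pan-neuronal genes at 21.8 distal peaks and Hox clusters at 0.103.

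Peaks covered more of the loci of astrocyte, oligodendrocyte, pan-neuronal, clock and immediate early genes than of random lists. The median share of the gene span and 10 kb flanks covered by peaks was 15.8% for astrocyte genes (SD 6.05, n = 20, permutation adjusted p = 0.0205), 15.2% for clock genes (SD 5.91, n = 22, permutation 0.0176), 15.1% for immediate early genes (SD 6.37, n = 22, permutation 0.0249), 15.1% for oligodendrocyte genes (SD 5.68, n = 20, permutation 0.0249) and 14.2% for pan-neuronal genes (SD 6.22, n = 24, permutation 0.0249). Random lists matched on gene length had medians of 8.84, 8.13, 8.13, 8.70 and 8.11%. Hox genes had a median of 0.0% (SD 1.57, n = 39) against 8.80% (permutation adjusted p = 0.0176). The other 16 lists did not pass, with adjusted permutation p from 0.0735 to 0.958. Among them, hypothalamic factors had 12.3% against 8.79% (permutation adjusted p = 0.146), and passed without flanks, with 19.6% against 9.55% (permutation 0.00147). The clock and Hox calls were lost without flanks (12.5% against 8.14%, permutation 0.245, and 0.0% against 10.8%, permutation 0.106). Single loci with high cover were Hcrt at 25.3%, Avp at 23.8% and Mapt at 21.8%, against 2.57% for Sim1 and 1.70% for Esr1.

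The clusters of distal peaks with the most covered sequence overlapped protein-coding genes, and several ran past the ends of the gene. Joining distal peaks closer than 12.5 kb gave 30894 domains, and each of the 20 with the most covered sequence overlapped a protein-coding gene. The first was at the axon guidance gene Nav2 on chromosome 7 (48886990 to 49617478), with 148.655 kb covered, followed by Snx29 with 103.721 kb, Agap1 with 101.294 kb, Ank2 with 81.568 kb and Gse1 with 81.258 kb. The neural transcription factor gene Myt1l, the adhesion genes Cadm1, Kirrel3, Dscam, Dscaml1 and Igsf21, and Farp1, Cacna1c, Ttc7b, Msi2, Tnik, Arid1b, Frmd4a, Kalrn and Tmem178b completed the 20, the last with 69.547 kb. Of 24 pan-neuronal genes, 4 (16.7%, Wilson 95% interval 6.68 to 35.9) were nearest to 1 of the top 500 domains against 2.17% of other genes (exact adjusted p = 0.0371). Genes nearest to these domains had a median length of 190.657 kb, against 16.604 kb for other genes, and against random lists matched on gene length the pan-neuronal call was lost (4.17% in random lists, permutation adjusted p = 1.0). The other 21 lists had 0 to 2 such genes, each with an exact adjusted p of 1.0.

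The 10 peaks of highest fold had folds of 25.3 to 27.97, and 7 of them overlapped a protein-coding gene. The first overlapped Lipo3 on chromosome 19 (33589519 to 33590221), with a fold of 27.97. Ldah (27.8), Lrr1 (26.8), the nuclear pore gene Nup85 (26.6), Mmadhc (26.5), the DNA repair gene Exo1 (26.4) and Gm40469 (25.3) also overlapped their peak, the peaks at Ldah and Mmadhc overlapping a long noncoding RNA as well. The other 3 lay 6492 bp from Zkscan8, 11110 bp from Gm35315 and 39982 bp from Gm15319, with folds of 27.7, 27.2 and 27.7. The Zkscan8 and Gm15319 peaks overlapped the pseudogenes Zfp389 and Gm20583, so their reads are uncertain.

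The X chromosome held far fewer peaks than any autosome. It had 14.6 peaks per Mb, against 73.7 ± 6.71 (SD, n = 19 autosomes, range 61.6 to 88.3), the lowest of these 20 chromosomes (two-sided exact permutation p = 0.05, the smallest that 20 chromosomes allow). Distal peaks were at 10.8 per Mb against 63.3 ± 5.03 (exact permutation p = 0.05), and peaks at gene ends at 2.77 against 6.71 ± 1.77 (exact permutation p = 0.1). The gap was smaller for peaks of fold 10 or more, at 1.51 against 2.66 ± 0.480 (exact permutation p = 0.1). Protein-coding genes were at 5.66 per Mb against 8.48 ± 2.46 (exact permutation p = 0.35). Of 966 protein-coding genes on X, 49.4% had a peak at an end (Wilson 95% interval 46.2 to 52.5), against 71.9% ± 5.75 on the autosomes. Folds at marked X genes had a 90th percentile of 14.7 against 14.8 ± 0.664 (exact permutation p = 0.95, not distinguishable). Among the X genes looked up for having a partner on Y, Eif2s3x had 18.7, Kdm6a 11.04, Kdm5c 10.7, Ddx3x 8.35 and Usp9x 7.37. The Y chromosome held 6 peaks, between positions 90723693 and 90744738, and Ddx3y, Uty, Kdm5d, Eif2s3y, Zfy1 and Usp9y had none.

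**Figure D4:**
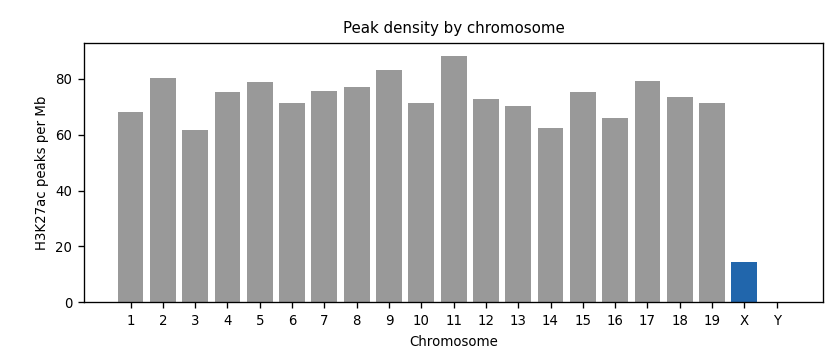
H3K27ac peaks per Mb of annotated chromosome span for each chromosome, with X and Y in blue and autosomes in grey. X had 14.6 peaks per Mb and Y 0.0660, below the autosome range of 61.6 to 88.3.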

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

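No paired analysis was possible because the 3 bulk replicates share 1 peak list and no groups are compared. For the same reason no replicate could be left out. The tests over the gene span, with summits nearer to the gene than to any other, on autosomes only, and of domains against lists matched on gene length were chosen after the data had been seen. For each change below the cause was not tested, and depth, which is unknown, limits the calling of weak peaks throughout.

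Of 198 comparisons of the share of marked genes with the chosen settings, 159 kept their direction and their side of the threshold. With windows of 500 bp, neurotransmitter genes (60.0%) and choroid plexus (60.0%) fell below other genes. With windows of 2500 bp, hypothalamic factors (94.4%) and astrocytes (100.0%) passed and hindbrain and midbrain factors (46.7%) no longer did. With peaks above the median −log10 q, immediate early genes (86.4%) no longer passed, astrocytes (90%) passed, and neuropeptides (62.5%), hypothalamic factors (55.6%), neurotransmitter genes (55.0%), microglia (47.6%) and choroid plexus (40.0%) fell below other genes.

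With peaks at or above the upper quartile of fold, 3 lists passed as higher, receptors (66.7%) and immediate early genes (77.3%) no longer passed, and 7 lists fell below other genes: neuropeptides (46.9%), hypothalamic factors (41.7%), neurotransmitter genes (40.0%), oligodendrocytes (55.0%), their precursors (57.1%), microglia (33.3%) and choroid plexus (20.0%). With the summit inside the window, 3 lists passed as lower, hindbrain and midbrain factors (40.0%) and other organs (44.0%) no longer passed, and neurotransmitter genes (65.0%) fell below other genes. Choroid plexus, at 70.0%, fell below other genes with a background without chemosensory receptors and, again at 70.0%, on autosomes only.

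Over the gene span and 1 kb around it, hypothalamic factors (97.2%), astrocytes (100.0%) and oligodendrocyte precursors (100.0%) passed, hindbrain and midbrain factors (60.0%) did not, and cortical factors (86.7%) and endothelial genes (88.2%) rose above other genes. With summits nearer to the gene than to any other, 2 lists passed as lower. Hindbrain and midbrain factors (33.3%), clock genes (77.3%), immediate early genes (77.3%), pituitary (25.0%) and other organs (40.0%) no longer passed, and cortical factors (60.0%) and endothelial genes (58.8%) rose above other genes.

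Of 88 comparisons of fold, 68 were the same. With the highest −log10 q in place of fold, immediate early genes (126) no longer passed, tanycytes (70.9) passed as lower, and pan-neuronal (227) and clock genes (239) lay above random lists. With the widest peak, 1 list passed as higher and 6 as lower. Hindbrain and midbrain factors (962.5 bp), neurotransmitter genes (974.5 bp), oligodendrocytes (1163 bp), endothelial genes (1026 bp), pituitary (675 bp) and other organs (1204 bp) no longer passed. Above random lists lay pan-neuronal genes (1722 bp), receptors (1447 bp), clock genes (1457 bp), immediate early genes (1393 bp), astrocytes (1308 bp), tanycytes (1319 bp) and oligodendrocyte precursors (1658 bp). With windows of 2500 bp, receptors (6.601) and immediate early genes (6.53) no longer passed and Hox genes (3.47) did.

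Of 88 comparisons of distal peaks, 77 were the same. Within 50 kb, 1 list passed as higher, neuropeptides (2.03) and pan-neuronal genes (13.04) no longer passed, and choroid plexus (5.50) lay above random lists. Within 500 kb, 1 list passed as higher and 2 as lower, neuropeptides (4.03), oligodendrocytes (13.1) and blood (0.375) no longer passed, and neurotransmitter genes (6.80) lay below random lists. With peaks above the median −log10 q, 2 lists passed as lower, neuropeptides (1.34) and blood (0.0625) no longer passed, and pituitary (2.33) lay above random lists. On autosomes only, neurotransmitter genes (6.70) lay below them.

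Of 66 comparisons of coverage, 50 were the same. Without flanks, 0 lists passed as lower, Hox (0.0%) and clock genes (12.5%) no longer passed, and hypothalamic factors (19.6%) did. Cortical factors (17.7%) and neurotransmitter genes (8.45%) then lay above random lists, and microglia (8.94%), choroid plexus (7.99%) and other organs (0.0%) below. With peaks above the median −log10 q, cortical factors (6.45%) lay above random lists and neuropeptides (5.70%), microglia (4.502%) and choroid plexus (5.00%) below. On autosomes only, 3 lists passed as lower, among them hindbrain and midbrain factors (1.302%) and pituitary (2.13%), and choroid plexus (8.96%) and other organs (7.49%) lay below random lists.

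Of 88 comparisons of domains, 79 were the same. With distal peaks joined over a shorter distance, 0 lists passed and pan-neuronal genes (8.33%) no longer did. Cortical factors (0.0%) and clock genes (0.0%) then lay below other genes, and neurotransmitter genes (5.00%) and astrocytes (5.00%) above. With the top 1000 domains, hypothalamic factors (2.78%) lay below and astrocytes (10.0%) and pituitary (8.33%) above. Against random lists matched on gene length, 0 lists passed and pan-neuronal genes, at 16.7%, no longer did. Among peaks above the median −log10 q, 14.6% lay at gene ends, 57.9% inside genes, 6.82% in other genes and 20.7% between genes. X kept its lower density among those peaks, with 7.90 per Mb against 37.1 on the autosomes (exact permutation p = 0.05).

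In the alternative written as the majority of the interval, its midpoint was used. Merging of intervals tests nothing for distal peaks or density, since none overlap or touch. The longest transcript, CpG matching and the motif and CpG alternatives were not run, for want of sequence and transcripts.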

Other observations

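Gene families were also compared by symbol. Some of their members, such as Pax6 and Rpl4, are in the fixed lists too, so part of these results repeats those of the lists, and the 20 families, like the tests of the X chromosome and of Y in peak calling below, were chosen after the data had been seen. Chemosensory receptor families were almost without the mark. A peak at an end was found for 19 of 1110 olfactory receptor genes (1.71%, Wilson 95% interval 1.1 to 2.66, exact p too small to compute), 4 of 353 vomeronasal receptor genes (1.13%, Fisher's exact test, adjusted p = 7.95e-173) and 0 of 35 bitter taste receptor genes (Wilson 95% interval 0.0 to 9.89, exact adjusted p = 6.75e-18). Keratins had 15 of 53 (28.3%, exact adjusted p = 2.98e-09), cytochromes P450 34 of 99 (34.3%, 3.47e-12, exact), beta-defensins 2 of 42 (4.76%, exact adjusted p = 6.75e-18) and PAX factors 1 of 9 (11.1%, exact adjusted p = 8.79e-04). Members of the chemosensory families are similar in sequence, and their mappability was not tested.

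Several families of basic cell function and of neuronal signalling, though not all that were tested, were marked more often than other genes. Complex I subunits had 47 of 49 genes marked (95.9%, exact adjusted p = 1.43e-05), ribosomal proteins 72 of 77 (93.5%, 8.27e-07, exact), proteasome subunits 47 of 51 (92.2%, exact adjusted p = 2.28e-04) and zinc finger proteins 339 of 397 (85.4%, 2.62e-13, exact). Glutamate receptors had 25 of 27 (92.6%, exact adjusted p = 0.00858), potassium channels 79 of 94 (84.0%, 0.00239, exact), SOX factors 18 of 19 (94.7%, exact adjusted p = 0.0163) and solute carriers 292 of 375 (77.9%, 3.44e-04, exact). GABA-A receptor subunits (16 of 19), serotonin receptors (13 of 14), acetylcholine receptors (15 of 21), clustered protocadherins (36 of 57) and forkhead factors (30 of 46) did not pass, with exact adjusted p from 0.0980 to 1.0. The median fold of marked members was 12.4 for proteasome and 12.3 for complex I subunits, against 5.47 for glutamate receptors and 5.54 for potassium channels.

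A lower gene content is argued against as the whole cause of the low number of peaks on X: X had 2.57 peaks per protein-coding gene, below the autosome range of 5.41 to 13.002. That value counts peaks of all folds, and the argument does not extend to peaks of fold 10 or more, for which no test per gene was run. X had 1.51 such peaks and 5.66 protein-coding genes per Mb. Chromosome 7 had 2.79 and 14.0, and chromosome 17 had 2.80 and 11.2, both fewer per gene than X, while the other autosomes had more. Without families of many copies and genes with provisional Gm or Rik symbols, X still had 22.6 distal peaks per Mb of the territories of the other genes, against 83.5 to 108 on the autosomes, which argues against such families as the whole cause of the low number. For the share of marked genes they stay open, since leaving these genes out raised X from 49.4% to 71.2% (Wilson 95% interval 67.6 to 74.6), and the lowest autosome had 75.2% (72.9 to 77.3). Fewer reads from X, in peaks and background alike, stay open: a test on the 90th percentile of fold, 14.7, was replaced after its value was seen, because the background behind a fold is not stated, and X peaks of fold 10 to 12 had a median −log10 p of 171 against 205 to 283, not below by the margin set, while at fold 5 to 6 the X value of 37.3 lay inside 37.2 to 46.6. Mappability and filtering of X were not tested, and no biological explanation was tested, since the samples form no groups that differ in it.

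No peak was found at the 6 Y genes that were looked up, while the X partners of 5 of them, all that were looked up, had one at an end. The labels used here give no sex. Xist, which is transcribed from the inactive X in females, had a peak of fold 5.97 at an end, which is consistent with tissue from female animals, a test written before that value was seen though after the empty Y had been. Omission of the whole Y chromosome from peak calling is argued against by the 6 peaks it holds, but these lie between positions 90723693 and 90744738, and a filter on the rest of Y, or its mappability, was not tested. A pool of both sexes is not excluded by Xist alone.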
